A study of Escherichia coli with 33 samples.

How the data were processed

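The series measured RNA structure in Escherichia coli MG1655 by mutational profiling, in which a chemical adduct on a base makes reverse transcriptase write a wrong base into the cDNA, so that the share of reads with a mutation at a nucleotide rises with its reactivity. Cells in mid-exponential growth in LB were exposed for 5 min to ETC (a reagent for G and U, per the labels), to dimethyl sulfate (DMS, which methylates the pairing face of A and C) or to neither. All 33 libraries were used. Of these, 12 are single libraries that test the reverse transcription step. Untreated RNA and RNA from 200 mM ETC were copied with HIV-RT, SuperScript-II, Marathon or TGIRT-III, the last at 65 or 70 °C. RNA from 300 mM ETC and from 100 mM DMS was copied with TGIRT-III at 65 °C. The other 21 form 7 groups of 3 biological replicates, lettered A, B and C, all with TGIRT-III: untreated and ETC at 50, 55 and 60 °C, and DMS at 55 °C. The labels give no reagent dose for these 21. Per the labels, cells treated with ETC resisted standard lysis and were broken with more lysozyme and with beads, whereas untreated and DMS-treated cells were not, so lysis and ETC treatment cannot be separated in any ETC comparison.

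Per the file headers, each deposited profile lists, for every nucleotide, raw counts of mutated reads. The authors also give 2 coverage signal columns, the effective depth (reads usable for calling a mutation) and the read depth, neither of them normalized. The authors' reactivity score is the treated minus the untreated mutation rate, which was checked against their rates, and their normalized reactivity score is that value times 1 factor per RNA, by a method they do not state. The submitters' notes name cutadapt and Bowtie2 without versions. The mutation caller, the mutation filter and the source of the sequences are not stated, so positions are those of the 16S (1542 nucleotides), 23S (2904) and 5S (120) rRNA as the files number them, and no genome coordinates are given. Of 39 profiles, 14 pairs are identical, and 185 of 624 columns of values were used; the 439 others repeat a column, can be computed from those used, or are not used here. The pooled profiles of the authors hold the same reads as the replicates (identical read depth, the untreated columns at 60 °C aside) but different mutation counts, and the untreated columns of the pooled 60 °C profile are identical to those of 55 °C, so the pooled profiles served as alternatives at 50 and 55 °C alone. The names of the triplicate profiles mark them as filtered, whereas those of the single libraries carry no such mark. What the filter removed is not stated, so rates of the triplicate libraries may leave out part of the signal. The triplicate and the single libraries differ in untreated mutation rates at the same bases, and were compared only within each set.

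A mutation rate is mutated reads over effective depth, in percent, and an added rate is the treated minus the untreated rate of the same letter, in percentage points; its mean does not depend on which letters are set against each other, but its SD does. Nucleotides with an effective depth of at least 5000 in all 6 libraries of a comparison were tested, which left 4444 in each of the 4 comparisons (1399 G, 904 U, 1150 A and 991 C) and none of the 5S rRNA, whose median depth was 1538 to 10027. Median effective depth was 216191 to 949012 per triplicate library and 146282 to 529632 per single library, and the mutated reads per library numbered 3013336 to 18403653 and 2165527 to 18035454. Rates of single libraries have 95% exact Clopper-Pearson intervals, which cover counting error only, since the reads carry no molecular identifiers. For the test, limma 3.58.1 (R 4.3.3) was fitted to log2 odds of mutation with 0.5 added to mutated and unmutated reads, with a trended prior. A nucleotide was called reactive when its Benjamini-Hochberg adjusted p was under 0.05 over all tested nucleotides and its log2 odds rose by at least 1, and lower when they fell by at least 1. The temperature interaction, the ETC effect at 60 °C minus that at 50 °C, was tested in 1 limma fit with p adjusted over all 4444 nucleotides, and calls were counted among the 125 reactive at 50 or 60 °C. On simulated data with the depths of the 50 °C libraries and 200 of 4444 nucleotides changed, limma recovered 100% of changes of 1.5 and of 3 in log2 odds with 0 false calls, the quasi-binomial model 99% and 100%, and edgeR 100% and 100%. The simulation gave all nucleotides 1 common spread, with no shift of whole libraries. It therefore checks the fits, and does not measure power or false calls in the real data.

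Mean added rates by base were compared with exact two-sided permutation tests, which with 3 against 3 libraries cannot go below 0.1. The area under the curve (AUC) is the chance that a nucleotide outside a listed 16S helix has a higher added rate than one inside, computed per base and letter and averaged. It was tested with an exact two-sided permutation test over all 1542 circular shifts of the helix map along the RNA, whose smallest p is 0.000649. On 1542 simulated normal values, the measured area differed from the expected one by at most 0.00984. That simulation used no rates, bases or helices of the 16S rRNA, and checks the computation alone. The helices (74 segments, 387 pairs, 774 nucleotides) were listed from general knowledge of the 16S secondary structure and had no pair other than G-C, A-U and G-U in the sequence of the files; the 768 nucleotides outside them include some that pair in other ways. Minimum free energy folds of the 16S rRNA were computed with ViennaRNA 2.7.2, with each library's added rates (G and U for ETC, A and C for DMS) divided, per base, by the mean of the values between the 90th and 98th percentile, values under 0 set to 0, and turned into pseudo-energies with slope 1.8 and intercept -0.6. Sensitivity is the percent of the 381 listed pairs without pseudoknots that a fold holds, and positive predictive value the percent of its pairs that are listed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and edgeR 4.0.16 were also used.

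Groups, tests, thresholds, helices and lists were fixed before the data were examined. The named nucleotides are, among reactive ones with every treated library above every untreated one, the 6 G, 6 U, 3 A and 3 C (ETC) or 6 A, 6 C, 3 G and 3 U (DMS) with the largest mean added rate, and up to 4 members of each list with the largest change that passed. The lists are modified bases whose modification lies on the pairing face or blocks it (11), other modified bases (25), the decoding centre and P site (10), the anti-Shine-Dalgarno sequence (6), the peptidyl transferase centre with the tRNA-binding loops (13), the sarcin-ricin loop (4), the GTPase centre (2), the loop of 23S helix 69 (6), and 16S GNRA (32) and UUCG-type (16) tetraloops, all written from general knowledge and all measured in full. The alternatives were an effective depth of 1000 or 20000, a quasi-binomial model, edgeR, a pseudocount of 5, no minimum change and leaving out nucleotides with an untreated rate over 5%. Others were the letter as a replicate block, leaving out each library, the pooled profiles and normalized reactivity of the authors, and medians in place of means. Hairpin loops alone, terminal pairs left out and no subtraction were also used. In the fold, they were a slope of 2.6 with an intercept of -0.8, a slope of 1 with an intercept of -0.3, and all 4 bases. Added after seeing the data were log2 odds centred on each library's median (list counts included), ETC library A alone at 55 °C, 3 further fits of the interaction and its adjustment over the 125 alone. Also added then were ETC at 50 °C and leaving out letters in the fold, G and U against the mean of A and C, and the adjusted p of added rates, AUC and helix counts.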

Results

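Mutation rates at single nucleotides of the 16S, 23S and 5S rRNA were measured in 33 libraries of E. coli RNA, with 3 biological replicates in each of 7 groups and 1 library in each of 12. The study names 2 questions: which reverse transcription condition detects ETC adducts, and whether ETC, alone or with DMS, improves the prediction of RNA structure. Over all nucleotides, the mutation rate was 0.255% to 0.874% in the triplicate libraries and 0.268% to 0.911% in the single ones.

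With ETC and reverse transcription at 50 °C, 47 of 1399 G and 66 of 904 U had a higher mutation rate than in untreated cells, against 2 of 1150 A and 3 of 991 C. Of the U called, the largest added rate was that of 23S U2474, at 1.91% ± 0.380 with ETC against 0.213% ± 0.0333 without (SD, n = 3 in each group). It was followed by 23S U1523, at 1.52% ± 0.308 against 0.192% ± 0.00893, and 23S U92, at 1.31% ± 0.258 against 0.0437% ± 0.0018. The G were lower in level. 23S G1573 was at 0.492% ± 0.111 against 0.0426% ± 0.00461, and 16S G1278 at 0.473% ± 0.102 against 0.0454% ± 0.0137. 16S G791, in the loop of the 16S platform that faces the P site, was at 0.342% ± 0.130 against 0.0365% ± 0.00903. The other named G and U, 23S G389, G548 and G2112, 23S U653 and 16S U485 and U121, had added rates of 0.118 to 1.22 percentage points. The A and C called were 16S C1397, A1398, C1399 and C1400, a run of neighbours in the decoding region, and 23S A2883, with added rates of 0.0643 to 0.428 percentage points. A1398 was not called when ETC library A, ETC library B, untreated library A or untreated library B was left out.

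Some functional sites of the ribosome were reactive to ETC at 50 °C. In the decoding centre and P site list, 3 of 10 members rose. G530, which monitors the codon-anticodon helix, rose by a log2 odds difference of 3.09 ± 0.20 (SE), G1401 by 2.39 ± 0.28 and C1400 by 1.37 ± 0.18. In the peptidyl transferase list, 3 of 13 rose. These were U2585 by 2.12 ± 0.16, G2553 of the A loop, which pairs with A-site tRNA, by 1.46 ± 0.18, and G2253 of the P loop by 1.17 ± 0.14. Of the tetraloops, 16S G1516 and G1517 made up the 2 of 32 GNRA members that rose, and U209 and U421, both at the second loop position, the 2 of 16 UUCG-type members. None of the 4 sarcin-ricin, 2 GTPase centre and 6 helix 69 nucleotides was called, and their median log2 odds differences were 0.39, 0.09 and 0.11; the GTPase centre and helix 69 lists hold only A and C. In the anti-Shine-Dalgarno sequence, which base-pairs with mRNA, 3 of 6 nucleotides fell: U1537, C1538 and U1540, the last from 3.70% ± 0.429 to 1.24% ± 0.00952. In the unfiltered pooled profile of the authors, U1540 was instead higher with ETC (3.49% against 0.302%, effective depth 573 with ETC). At 55 °C so were U1540 (2.46% against 0, depth 203 with ETC) and U1537 (3.14% against 0, depth 287 with ETC). Of the modified bases, 1 of 11 with a modification on the pairing face rose (m2G1516, also counted among the tetraloops) and 1 of 25 others fell (ho5C2501, from 8.53% ± 4.73 to 2.76% ± 1.03, a level that differed widely between untreated letters). Adjusted over the list alone, each count at 50 °C was the same, and relative to the library medians C1535 also fell.

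Calls by limma at 50 °C rest on adjusted p of 0.00342 or less among the nucleotides named for their added rate, those named only as list members aside. At the unadjusted threshold, 212 G, 180 U, 73 A and 47 C were higher, those called included. Without ETC library B, untreated library A or untreated library B, 1 A was called in place of 2. A lower rate was called at 14 G, 4 U, 0 A and 5 C, and without a minimum change 26, 6, 3 and 14 were lower. Averaged over all nucleotides of a base, the added rate was 0.00677 ± 0.00493 percentage points at G, 0.0291 ± 0.0316 at U, 0.00432 ± 0.0136 at A and -0.00391 ± 0.00756 at C. The ETC and untreated libraries overlapped at each base (exact permutation p = 0.3, 0.4, 0.7 and 0.7, adjusted 0.582, 0.582, 0.747 and 0.747 over 16 tests). With 3 against 3 libraries this test cannot go below 0.1, so it could not have passed 0.05 at any base. The unfiltered pooled profile of the authors gave 0.0376 at G, 0.0631 at U, 0.00845 at A and 0.00312 at C.

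**Figure D1:**
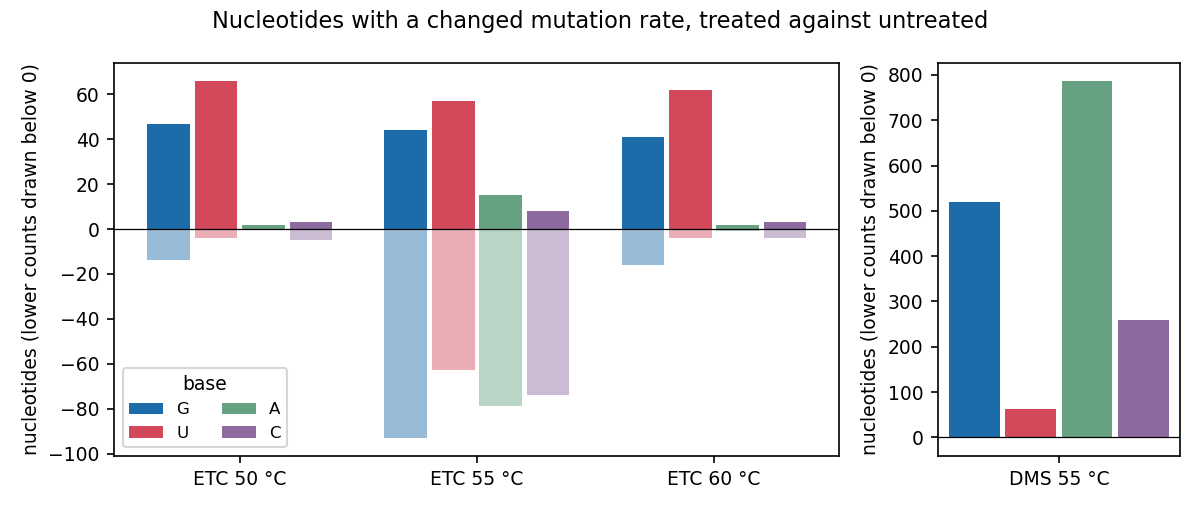
Number of nucleotides called higher (bars above 0) or lower (paler bars below 0) than in untreated cells, by base, for ETC at 3 temperatures and DMS at 55 °C, on separate vertical scales on which counts of 1 are barely visible. With ETC, 41 to 47 G and 57 to 66 U were higher; at 55 °C, 309 nucleotides were also lower, and with DMS 787 A were higher.

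**Figure D2:**
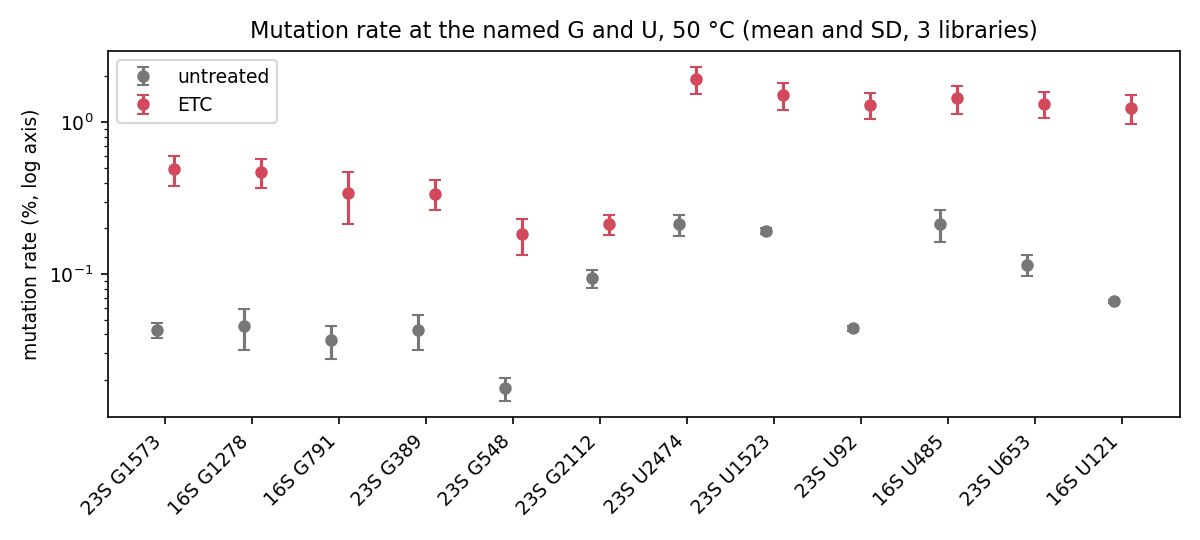
Mutation rate in percent on a log axis at the named G and U at 50 °C, in untreated cells (grey) and with ETC (red), as mean and SD of 3 libraries. The ETC rates run from 0.183% at 23S G548 to 1.91% at 23S U2474, each above its untreated rate.

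At 60 °C, 41 G, 62 U, 2 A and 3 C were reactive to ETC, and at 55 °C 44 G, 57 U, 15 A and 8 C. 23S G1573 had an added rate of 0.391 ± 0.0917 percentage points at 55 °C and 0.377 ± 0.0982 at 60 °C. For 16S G1278 these were 0.380 ± 0.114 and 0.405 ± 0.114, and for 23S U2474 1.76 ± 0.580 and 1.8 ± 0.319. The lists for 50 and 60 °C shared 38 G (1.38 expected from the list sizes), 59 U (4.53 expected), 1 A and 3 C, and 25 G, 47 U, 1 A and 3 C were called at all 3 temperatures. The same letters may mark the same RNA at each temperature, so these are not independent cultures. G530, C1400, G1401, U2585, G2553 and G1517 were called at all 3. At 60 °C, 3 of 10 decoding, 3 of 13 peptidyl transferase, 1 of 32 GNRA and 3 of 16 UUCG-type nucleotides rose, 3 of 6 anti-Shine-Dalgarno nucleotides fell, and no other list had a call (relative to the library medians, C2501 also fell). At 55 °C, 4, 2, 1 and 0 of these rose. In the lists at 55 °C, 4 anti-Shine-Dalgarno, 2 of 25 other modified, 1 of 2 GTPase centre, 2 GNRA and 2 UUCG-type nucleotides fell. The median of all nucleotides was also lower there, by 0.43, and relative to the library medians 3 anti-Shine-Dalgarno and 1 UUCG-type nucleotides fell, and 6 decoding, 2 peptidyl transferase, 2 GNRA, 1 UUCG-type, 1 of 11 and 1 of 25 modified nucleotides rose. Adjusted over the list alone, 3 GNRA members fell at 55 °C and the other counts were the same.

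Other named sites at 55 °C lay at the 3′ end of the 23S rRNA, where these nucleotides had a lowest depth of 18695 to 43755 reads. U2897 was at 3.46% ± 0.918 against 1.29% ± 0.156, and U2898, A2893, G2892 and G2894 were also called. 23S U653 was at 1.37% ± 0.250 against 0.117% ± 0.0104. 23S U1523, 16S U485 and 23S G389 had added rates of 0.298 to 1.14 percentage points, and 16S G791 of 0.280 ± 0.133. The named A and C at 55 °C were also 23S A1420 and A2821, 23S C2442 and C2443 and 16S C1397, with added rates of 0.517 to 2.45 percentage points. Without ETC library B none of these 5 was called, nor U2898. U2898 and A2821 also lost the call without ETC C, untreated A or untreated C, U2898 and C2443 without untreated B, and C2442 and C2443 without untreated C. At 60 °C the others were 16S G791, G530 and U485, U121, 23S G389, G548, U1523, U2473 and U653 (0.126 to 1.19 percentage points), 23S A2799 and A2883, and 16S C1397, C1399 and C1400 (0.0612 to 0.407). Without ETC B or untreated B none of these A and C was called. A2799 and A2883 also lost the call without ETC C or untreated C, and C1399 and C1400 without ETC A.

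The counts at 55 °C depended on single libraries, untreated ones included, and 2 ETC libraries had a lower level. The median log2 odds over all nucleotides was -10.0 in ETC library A, -10.7 in B and -10.7 in C, against -9.91 to -10.2 in the untreated libraries, and the median difference between groups was -0.43, against 0.06 at 50 °C and -0.01 at 60 °C. Lower rates were called at 93 G, 63 U, 79 A and 74 C at 55 °C, so that 28.6% of all calls were higher. Relative to each library's median, 98 G, 93 U, 39 A and 27 C were higher and 31, 20, 23 and 18 lower, and 73.6% were higher. Leaving out 1 library moved the G count from 44 to 12 (without ETC B or untreated C), 13 (untreated A), 15 (untreated B) or 25 (ETC C), and the U count from 57 to 36 (ETC B) or 35 (any untreated library). It moved the A count from 15 to 1 (ETC B), 2 (untreated A or C) or 3 (ETC C or untreated B). It moved the C count from 8 to 2 (ETC B), 3 (untreated C), 4 (untreated B) or 13 (ETC A). At 60 °C, the G count fell from 41 to 22 without ETC B and 23 without ETC A. The A count fell to 0 without ETC B, untreated B or untreated C, and the C count from 3 to 0 without ETC B or untreated B and 1 without ETC A. Relative to the library medians, 0 A were called at 60 °C and 1 at 50 °C.

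No difference between 50 and 60 °C was detected in the response to ETC. Of the 125 nucleotides reactive at either, limma called 0 higher and 0 lower at 60 °C, with 1 and 2 at the unadjusted threshold. By edgeR, 0 and 0 were also called, with 1 and 2 unadjusted. With the letter within treatment as a replicate block, 0 and 0 were called, with 3 and 13 unadjusted. Adjusted over the 125 alone, 0 and 0 were called. The median interaction was -0.17 in log2 odds with a median SE of 0.31. The largest change of the 125, -1.06 ± 0.36 (SE) at 23S U92, was not called, so changes of this size can go undetected. Mean added rates were -0.00543 ± 0.0114 percentage points at G, -0.0358 ± 0.0355 at U, -0.047 ± 0.0308 at A and -0.0344 ± 0.0153 at C at 55 °C. At 60 °C they were 0.0011 ± 0.00835, 0.00733 ± 0.0228, -0.0105 ± 0.0193 and -0.0155 ± 0.0152. The smallest exact permutation p of these 8 was 0.1, the smallest possible, at C at 55 °C. A contrast chosen after the libraries' overall rates were seen took the mean of A and C from G and from U. At 55 °C it was 0.0353 ± 0.0117 percentage points at G (3 letters above 0) and 0.0049 ± 0.0128 at U (2 letters above 0). In the unfiltered pooled profile of the authors, the added rates at 55 °C were above 0 at G (0.0549) and U (0.0456), and in their filtered one at U (0.0144).

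DMS changed far more of the rRNA: 787 of 1150 A, 260 of 991 C, 519 of 1399 G and 63 of 904 U were higher than in untreated cells at 55 °C, and 1 G and 1 U were lower. The largest added rate was at 16S A915, with 69.2% ± 4.96 against 0.668% ± 0.0950 (n = 3 in each group), followed by A432 at 27.8% ± 7.49 against 0.307% ± 0.0418, and 23S A340 at 26.6% ± 8.41 against 0.0809% ± 0.0198. A1640 and A2749 of the 23S and A1261 of the 16S rRNA were at 20.5% to 23.6%. Among C, 23S C2306 was at 16.7% ± 4.00 against 0.257% ± 0.0194, and C1965, C2254, C1942, C1941 and C901 had added rates of 10.4 to 13.2 percentage points. The named G and U were lower, with 23S G1131 at 5.23% ± 2.46 against 0.0736% ± 0.0166. The others were 16S G867 and 23S G512 at 2.54% and 1.82%, and 16S U1381, U828 and U677 at 1.22% to 1.78%. U828 was not called relative to the library medians. 16S G867 and 23S G512 were also among the nucleotides whose rate was lower with ETC than in untreated cells.

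DMS marked many of the listed functional sites. All 6 listed A and C of the helix 69 loop, which bridges the subunits, rose, led by A1916 by a log2 odds difference of 4.15 ± 0.21 (SE), A1913 by 4.07 ± 0.27, A1918 by 3.78 ± 0.16 and C1914 by 3.43 ± 0.29. Over all tested nucleotides, 68.4% of A and 26.2% of C were called. Both listed A of the GTPase centre rose, A1067 to 6.20% ± 1.53 from 0.227% ± 0.00567 and A1095 to 4.02% ± 0.944 from 0.288% ± 0.0318, as did 2 of 4 in the sarcin-ricin loop, A2660 to 5.68% ± 1.46 from 0.250% ± 0.0614 and G2655. In the decoding list, 8 of 10 rose, including A1492 and A1493 by 4.07 ± 0.18 and 4.08 ± 0.18, C1400 and A1339. In the peptidyl transferase list 6 of 13 rose, led by A2602 by 5.05 ± 0.22, A2062 by 3.92 ± 0.22 and A2451 by 3.15 ± 0.12. Of the 32 GNRA members 19 rose (C381 by 6.37 ± 0.25 and A190 by 5.30 ± 0.30 the most), of the 16 UUCG-type 11 (C210 by 4.55 ± 0.28), and of the 6 anti-Shine-Dalgarno nucleotides 3 (C1535, C1536 and C1539). Of the modified bases, A1518 and G1516 were the 2 of 11 with a modification on the pairing face that rose, and C967, C1407, C1962 and C2498 the 4 of 25 others. The counts adjusted over the list alone were the same. Relative to the library medians, helix 69 and the GTPase centre kept 6 and 2, and 7 decoding, 3 peptidyl transferase, 1 sarcin-ricin, 1 anti-Shine-Dalgarno, 15 GNRA, 9 UUCG-type, 1 of 11 and 3 of 25 modified nucleotides rose. A1519, C2501, G1268 and U208 then fell. These falls are relative to a level that was itself higher with DMS (median log2 odds difference of all nucleotides 0.62). Without centring, no list member was called lower.

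The DMS calls by limma at nucleotides named for their added rate, those named only as list members aside, had adjusted p of 3.60e-05 or less. The median log2 odds difference of all nucleotides was 0.62, and relative to each library's median 505 A, 126 C, 171 G and 22 U were higher and 5, 25, 44 and 48 lower, so that the share of calls that were higher was 99.9% without and 87.1% with this centring. The mean added rate was 1.24 ± 0.358 percentage points at A, 0.379 ± 0.119 at C, 0.0490 ± 0.0120 at G and 0.0396 ± 0.0238 at U. The DMS libraries were all above the untreated ones at each base (exact permutation p = 0.1 for each, the smallest possible, adjusted 0.32 over 16 tests).

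With ETC, more of the G and U outside listed 16S helices were reactive than of those inside. Of the G outside helices 20 of 211 were reactive to ETC at 50 °C, against 3 of 276 inside (Fisher's exact p = 1.42e-05, adjusted 5.69e-05 over 16 tests, which take neighbouring nucleotides as independent). Of the U these were 20 of 142 against 2 of 172 (exact p = 5.85e-06, adjusted 3.12e-05). At 55 °C these were 13 G against 2 and 16 U against 2, and at 60 °C 16 against 3 and 20 against 1 (adjusted exact p of 0.00176 or less). With DMS, 217 of 277 A outside were reactive against 75 of 111 inside (exact p = 0.0368, adjusted 0.0653), and 73 of 137 C against 41 of 215 (exact p = 3.33e-11, adjusted 5.32e-10). Of the G these were 80 of 211 against 116 of 276 (exact p = 0.401, adjusted 0.494), and of the U 15 of 142 against 6 of 172 (exact p = 0.0212, adjusted 0.0423).

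By added rate, the AUC with ETC at 50 °C was 0.648 ± 0.0018 for G and 0.639 ± 0.0541 for U (SD over 3 letters; exact circular-shift permutation p = 0.000649, the smallest possible, and 0.0013, adjusted 0.00259 and 0.00346 over 16 tests). For A and C it was 0.534 ± 0.0302 and 0.506 ± 0.0443 (exact p = 0.161 and 0.835). At 60 °C it was 0.616 ± 0.057 for G and 0.606 ± 0.057 for U (adjusted exact p = 0.00259 and 0.00346), and at 55 °C 0.599 ± 0.0407 for G (adjusted exact p = 0.00445). For U at 55 °C, 0.554 ± 0.044 did not pass (exact p = 0.11, adjusted 0.195). By the unadjusted exact p, it passed without replicate C (0.576), with hairpin loops alone as the unpaired class (0.685), without terminal pairs (0.574) and with no untreated rate subtracted (0.647). The p of these alternatives was not adjusted. With DMS the AUC was 0.727 ± 0.0122 for A and 0.772 ± 0.00672 for C (adjusted exact p = 0.00259 for each), and 0.469 ± 0.0252 for G.

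**Figure D3:**
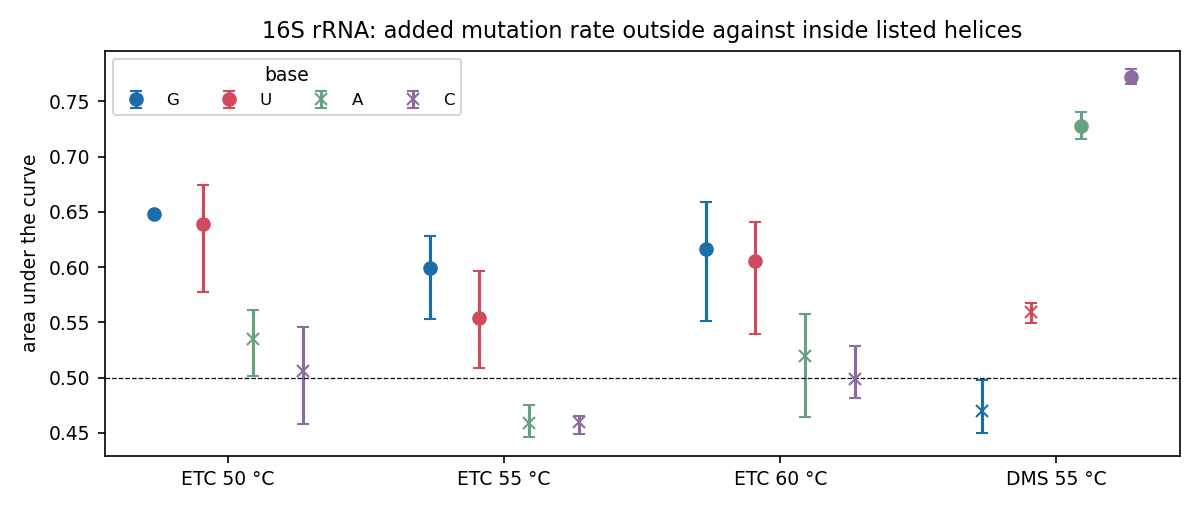
Area under the curve for telling 16S nucleotides outside listed helices from those inside by added mutation rate, by comparison and base, with the mean over 3 letters and bars from the lowest to the highest letter; circles are the bases a reagent is used for, crosses the others, and the dashed line is 0.5. The highest areas are 0.772 for C and 0.727 for A with DMS, and with ETC 0.648 for G and 0.639 for U at 50 °C.

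Folds of the 16S rRNA that used the reactivities held more of the 381 listed pairs than a fold without data. A value of 0 still gives a pseudo-energy, the intercept, which favours pairing. No fold with shuffled or constant values was run. How much of the gain comes from the reactivities, with either reagent or both, therefore cannot be told. The fold without data held 173 pairs (sensitivity 45.4%, positive predictive value 34.1%). With ETC at 55 °C the sensitivity was 51.5% ± 0.994 (SD, n = 3) and the predictive value 38.4% ± 0.462. With DMS at 55 °C these were 77.6% ± 0.152 and 58.8% ± 0.115, and with both 59.4% ± 2.29 and 44% ± 1.30. Each pair of data sets separated completely over the 3 letters (exact permutation p = 0.1, the smallest possible). The folds with both reuse the libraries of each reagent, and all sets share the untreated libraries. The test takes them as independent, so its p does not measure the error of the differences. The lead of DMS depended on the setting. With the normalized reactivity of the authors, sensitivity was 47.2% with ETC, 53.4% with DMS and 68.4% with both. That setting scales both reagents by the same factor (12.7 on the 16S rRNA), which leaves the ETC values small. Its ETC folds held 180 listed of 526 predicted pairs in each letter, so it cannot show what ETC reactivity adds to DMS. With a slope of 1 and an intercept of -0.3, which were changed together, sensitivity was 52.7% ± 3.97, 50.2% ± 0.606 and 50.7% ± 4.46, with overlapping letters. With all 4 bases of each reagent it was 58.9% ± 2.35 with ETC, 69.5% ± 1.52 with DMS and 57.1% ± 5.92 with both. With ETC at 50 °C in place of 55 °C it was 68.2% ± 6.66 for both.

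**Figure D4:**
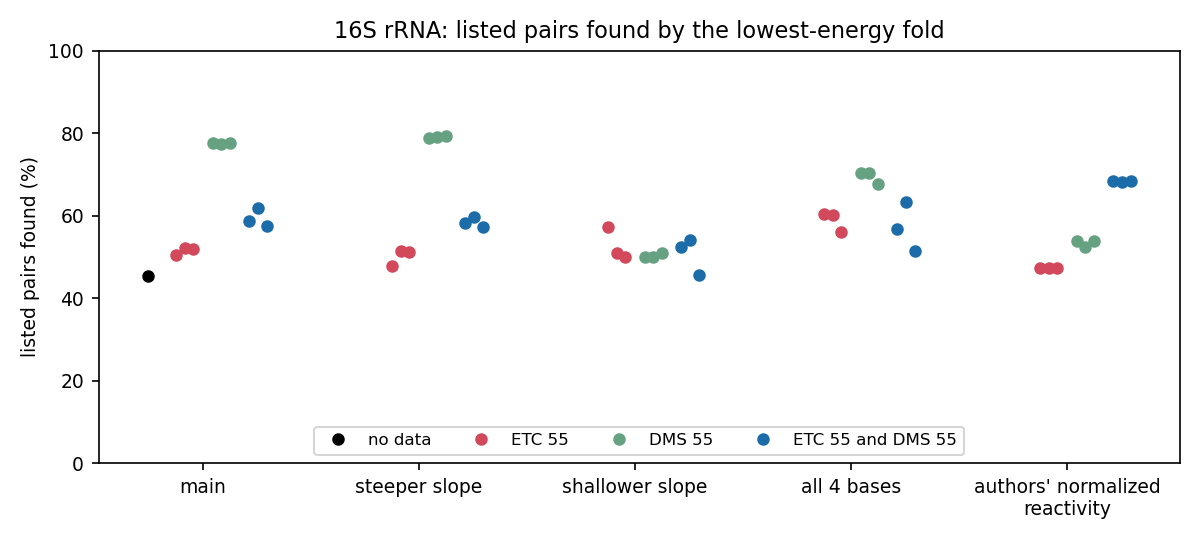
Percent of the 381 listed 16S pairs held by the lowest-energy fold, with 1 point per letter (without data, 1 fold). The settings on the axis are slope 1.8, 2.6 and 1 (intercept -0.6, -0.8 and -0.3), all 4 bases, and the authors' normalized reactivity. At the first setting DMS lies at 77.6% and both reagents at 59.4%. With the authors' normalized reactivity, DMS lies at 53.4% and both at 68.4%. There the ETC folds held 180 listed of 526 predicted pairs in each letter, so that setting cannot show what ETC reactivity adds.

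Single libraries compared 5 reverse transcription conditions, without replicates. The mean added rate at U was 0.126 percentage points with SuperScript-II, 0.116 with HIV-RT, 0.0731 with TGIRT-III at 65 °C, 0.0414 with Marathon and 0.0410 with TGIRT-III at 70 °C. The order depended on the measure. As medians over U, HIV-RT had 0.0693, TGIRT-III at 65 °C 0.0259 and SuperScript-II 0.0216, and over pooled reads HIV-RT had 0.109 and SuperScript-II 0.0970. At G it was 0.129 with HIV-RT and 0.0139 to 0.0337 with the others. HIV-RT also added 0.0501 at A and 0.0450 at C, where the others added -0.00163 to 0.0167. The AUC of the 16S rRNA for U was 0.757 with TGIRT-III at 65 °C, 0.736 at 70 °C, 0.729 with Marathon, 0.702 with SuperScript-II and 0.585 with HIV-RT. For G it was 0.682, 0.629, 0.636, 0.624 and 0.559 (adjusted exact permutation p over 28 tests of 0.0327 or less, except 0.0716 for HIV-RT at G). At A the AUC also passed with Marathon (0.601, adjusted exact p = 0.00389), and no other ETC condition passed at A or C (adjusted exact p of 0.0579 or more). At 16S U121, ETC rates were 1.55% (95% interval 1.51% to 1.59%) with TGIRT-III at 65 °C, 0.973%, 0.557%, 0.930% and 0.770% with the other conditions in the same order, against untreated rates of 0.0251% to 0.0390%. At 16S U485, HIV-RT gave 0.529% with ETC and 0.794% without. Differences between single libraries were not tested against replicate error, and the median added rate over U was below the mean in each condition, at 0.0145 to 0.0693.

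The ETC doses were compared by 1 library each. With TGIRT-III at 65 °C the mean added rate was 0.0149 percentage points at G and 0.0696 at U with 300 mM, against 0.0230 and 0.0731 with 200 mM, which share the untreated library. Over pooled reads it was -0.00882 and 0.0854 with 300 mM, against 0.0145 and 0.0794. The AUC for U was 0.768 with 300 mM and 0.757 with 200 mM, and for G 0.647 and 0.682. The single library of 100 mM DMS had added rates of 1.87 at A, 0.542 at C, 0.126 at G and 0.0241 at U, and an AUC of 0.723 for A and 0.775 for C (adjusted exact permutation p = 0.00227 for each).

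Some natural modifications on the pairing face gave mutations without reagent. The 11 such bases had a mean untreated rate of 24.5%, 24.1% and 24.1% with TGIRT-III at 50, 55 and 60 °C, and medians of 0.870%, 0.845% and 0.838%. In single libraries the mean was 23.7% with TGIRT-III at 65 °C, 22.2% at 70 °C, 18.4% with Marathon, 16.7% with HIV-RT and 16.2% with SuperScript-II, but by median HIV-RT (4.11%) and SuperScript-II (3.38%) lay above TGIRT-III at 65 °C (2.20%). With TGIRT-III, 4 of the 11 were over 5%. 23S m1G745 was at 85.1% ± 0.435 (SD, n = 3) and m3Ψ1915 (U in the files) at 88.6% ± 0.198 at 50 °C, and 16S m3U1498 at 76.4% ± 1.16 and m62A1519 at 16.1% ± 0.963. The 7 others were lower, m2G1516 at 0.0213% and the rest at 0.238% to 1.01%. In the single libraries, with intervals that cover counting error only, U1498 was at 61.5% (95% interval 61.2% to 61.8%) with TGIRT-III at 65 °C, 47.8% (47.3% to 48.3%) at 70 °C, 28.6% (28% to 29.3%) with Marathon, 38% (37.3% to 38.7%) with SuperScript-II and 32.6% (31.8% to 33.4%) with HIV-RT. A1519 was at 14.7% with TGIRT-III at 65 °C and at 0.719% to 1.15% with the 3 other enzymes. G745 was at 89.2% and 89.5% with TGIRT-III, 81.1% with Marathon, 51.2% with SuperScript-II and 53.7% with HIV-RT. The m2G bases 966, 1207, 1835 and 2445 lay between 1.28% and 2.25% with TGIRT-III at 65 °C, m62A1518 at 0.396%, and m2G1516 and m2A2503 at 0.131% and 0.0773%. The 25 other modified bases averaged 0.164% to 0.612%, with medians of 0.062% to 0.181% against 0.048% to 0.119% at all other nucleotides.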

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

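The values of the 5S rRNA, the tests of explanations and those of other splits were chosen after the results were seen, except the bound on the median of the 16S 3′ region, which was written before.

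Signals outside the main measurement were found in 3 places: the unfiltered pooled profiles of the authors at 2 temperatures, used as an alternative, and the 5S rRNA. In the pooled profiles, the mean added rate at G was 0.0376 percentage points with ETC at 50 °C (0.45% against 0.412% untreated). At 55 °C it was 0.0549 (0.441% against 0.386%). In the replicates, whose profiles are marked as filtered, these were 0.00677 and -0.00543. In the 5S rRNA, which was too thinly covered to be tested, the mean mutation rate at the 23 A was 0.824% ± 0.244 with DMS at 55 °C against 0.0856% ± 0.00241 untreated (SD, n = 3), with A109 at 7.92% ± 3.10 against 0.114% ± 0.0838 and A104 at 2.52% ± 0.571 against 0.355% ± 0.0962.

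The mutation rate at 16S m3U1498, a methylated base of the decoding region, was lower with ETC in 5 of 5 TGIRT-III conditions (76.4% to 68% at 50 °C, 75.3% to 67.3% at 55 °C, 72.4% to 63% at 60 °C, 61.5% to 52.8% at 65 °C and 47.8% to 39% at 70 °C) and in 2 of 3 other enzymes, with HIV-RT the exception (32.6% to 35.3%). The same letters at 50, 55 and 60 °C may mark the same RNA, and the single libraries may share RNA too. These conditions are therefore not independent tests. At 50 °C the log2 odds difference was -0.61 (limma adjusted p = 1.64e-06), which a lower rate everywhere cannot give, since the median over all tested nucleotides was 0.0645. A loss over the whole 3′ end stays open: the median over 51 unmodified nucleotides around U1498 was -0.089, above the bound, but that bound left aside that ETC raises G and U (7 of 29 called, median 0.17), whereas 19 of 22 A and C were below 0 (median -0.27, quartiles -0.39 to -0.16). Lysis cannot be told apart from ETC, since no ETC library was lysed like the untreated ones; with DMS the difference at U1498 was -0.0156. More 16S rRNA without its late modifications may be a source and stays open: A1519 was lower in 4 of 5 TGIRT-III conditions, the exception being a single library (10.7% to 13% at 70 °C).

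A set of 17 nucleotides, 14 of them G, was lower with ETC at both 50 and 60 °C outside the 16S 3′ end, where 4 more were. At 50 °C, to name members picked by their values, 16S C856 fell from 1.02% ± 0.288 to 0.0618% ± 0.00343, G867 from 0.603% ± 0.160 to 0.0476% ± 0.00401 and C271 from 0.375% ± 0.131 to 0.0432% ± 0.0129; with DMS, 14 of the 17 were higher than untreated, and 15 of the 17 were lower with ETC at TGIRT-III 65 °C. DMS-treated RNA or reads in the untreated libraries were ruled out as the whole source: the untreated share of the DMS excess was 20.5% at the set but 0.176% at the 12 named A and C. A single source present in a different amount in each untreated library may be behind the set. The excess over ETC in library C over that in B at 55 °C had a median ratio of 1.51. Of the set, 82.4% (14 of 17) lay within 25% of this ratio. At other nucleotides the ratio of the rates themselves, without subtraction, was 1.1, a different measure that cannot be set against 1.51. The bounds of this test were set after the ratios at 60 °C were seen, and 80% was the bound it passed. Lysis cannot be told apart from ETC here either; the set's median difference with DMS was 2.21.

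The rate at 23S ho5C2501, a hydroxylated C of the peptidyl transferase region, differed between letters in untreated cells, at 3.96% in A, 13.4% in B and 8.29% in C (means over 3 temperatures), at 1.66%, 3.12% and 3.36% with ETC, and at 4.50%, 8.40% and 6.37% with DMS (1 library each), which keep the untreated order of letters while ETC does not. The spread between letters was 19.5 times the largest within a letter, more than noise that differs from library to library gives. A preparation effect shared by the libraries of a letter stays open, since it would give the same pattern. A difference between the RNA samples that the letters mark is a candidate explanation. It rests on the same 9 libraries, with 99.9% of their variance between letters. No biological explanation was tested, and the 12 single libraries lay at 0.361% to 0.802%.

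For each of the 16 counts of reactive nucleotides, 1 of the 10 splits of the 6 libraries, the real one, gave as many, and the highest other split gave 0, against real counts of 2 to 787; 10 splits are too few for a share under 0.05. For the temperature interaction, where 0 nucleotides were called in each direction, 100 of 100 splits gave as many, as any split must, and the highest other was 0, so the splits say nothing about chance.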

How the results depend on the processing

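Centring on library medians, ETC library A alone, the further interaction fits and its adjustment over the 125 reactive nucleotides alone, ETC at 50 °C in the fold and leaving out letters in the fold were chosen after seeing the data; the cause of a change was not tested unless stated. The calls of nucleotides named for their added rate numbered 70 over the 4 comparisons, in which a nucleotide can count more than once. Of these, 56 were kept under every alternative fit, and none reversed. Nucleotides named only as list members are not among the 70. Same direction and side of the threshold, or a change within the spread, was found in 52 of 56 alternatives for the AUC, 107 of 116 for added rates, 12 of 23 for the fold. It was also found in 21 of 48 for native modifications and 37 of 84 for single libraries. For counts of reactive nucleotides, agreement meant a count within a fixed ratio of the main one, whatever the spread. By that rule 188 of 244 agreed. For example, 60 G at 50 °C without untreated library C passed as agreement with 47. For the temperature interaction, 54 of 54 gave the same count. The 5S rRNA was too thinly covered to be tested at a depth of 5000.

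Without a minimum change, which passes more nucleotides by construction, the counts for ETC were 86 G, 103 U, 13 A and 9 C at 50 °C, 27 A and 20 C at 55 °C, and 7 A and 6 C at 60 °C, and for DMS 901 G, 224 U and 546 C. Centred, they were 1 A at 50 °C, 98 G, 93 U, 39 A and 27 C at 55 °C, 0 A at 60 °C, and 171 G, 22 U, 505 A and 126 C with DMS. With ETC library A alone, where the spread comes from the untreated libraries only, 82 G and 16 C were called at 55 °C. The quasi-binomial model called 1 A at 50 °C and 0 A at 60 °C, a depth of 1000 called 1 A at 60 °C, and the letter as a replicate block 0 A at 60 °C. Leaving out 1 library gave 1 to 3 A at 50 °C. It gave 12 to 41 G, 35 to 52 U, 1 to 22 A and 2 to 13 C at 55 °C, and 22 to 45 G, 0 to 2 A and 0 to 3 C at 60 °C. With the letter as a replicate block, the interaction was 0 in each direction (3 and 13 unadjusted), and with the 12 libraries at 50 and 60 °C alone 0 (3 and 3 unadjusted). Adjusted over the 125 alone it was also 0 in each direction (1 and 2 unadjusted; smallest adjusted p 0.546). Whether the letters pair treated with untreated samples stays open: their same-letter correlation across nucleotides was -0.27 to 0.38, with 0.38 and 0.33 for A and B with ETC at 55 °C. Between 50 and 60 °C, over the 50 nucleotides most variable at 50 °C, it was 0.80, 0.79 and 0.88 for untreated A, B and C and 0.92, -0.39 and 0.73 for ETC, and over all tested nucleotides, which are not independent replicates, 0.12, 0.46 and 0.10, and 0.32, 0.064 and 0.30.

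In the unfiltered pooled profiles, added rates were 0.0376 at G and 0.0631 at U at 50 °C, and 0.0549 at G, 0.0456 at U, -0.0103 at A and -0.00934 at C at 55 °C; in the filtered one at 55 °C they were 0.0144 at U, -0.0087 at A and -0.00898 at C. The AUC for U at 55 °C was 0.685 with hairpin loops, 0.574 without terminal pairs and 0.647 with no subtraction, and 0.532 to 0.576 leaving out 1 letter.

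As medians over G, U, A and C, added rates were 0.0143, 0.0259, 0.00248 and 0.000848 with TGIRT-III at 65 °C (200 mM), and 0.00672, 0.0165, 0.0029 and -0.000889 (reversed) with 300 mM. They were 0.0292 at G, 0.0173 at U and 0.00694 at A with TGIRT-III at 70 °C, 0.0148, 0.0145, 0.00628 and 0.00298 with Marathon, 0.0216 at U and 0.000748 at A with SuperScript-II, and 0.118, 0.0693, 0.0338 and 0.0472 with HIV-RT. Without nucleotides of an untreated rate over 5%, they were 0.0905 at U and 0.00162 at A at 65 °C, 0.0134, 0.0869, 0.00248 and 0.00275 with 300 mM. They were 0.0541 at U, 0.0105 at A and 0.00871 at C at 70 °C, 0.0278 at G, 0.0427 at U and 0.0113 at A with Marathon, 0.0174 at G, 0.132 at U and 0.00695 at A with SuperScript-II, and 0.134 at G, 0.047 at A and 0.0504 at C with HIV-RT. A depth of 1000 gave HIV-RT 0.128 at G and 0.0484 at A.

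The medians of the 11 bases modified on the pairing face were 2.20% and 2.44% with TGIRT-III at 65 and 70 °C, 1.56% with Marathon, 4.11% with HIV-RT and 3.38% with SuperScript-II. With TGIRT-III at 50, 55 and 60 °C they were 0.870%, 0.845% and 0.838%. Without those over 5%, the means in the same order were 1.11%, 1.30%, 1.20%, 2.05% and 1.82%, then 0.437%, 0.438% and 0.417%. Medians of the 25 other modified bases were 0.0847%, 0.0620%, 0.0707%, 0.0945% and 0.114%, then 0.161%, 0.181% and 0.159%. Their means without those over 5% were 0.261%, 0.283% and 0.249% at 50, 55 and 60 °C.

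Fold sensitivity with ETC, DMS and both was 52.7%, 50.2% and 50.7% at slope 1 and intercept -0.3. At slope 2.6 and intercept -0.8 it was 50.1% and 79.0% with ETC and DMS. It was 58.9% and 69.5% with ETC and DMS for all 4 bases, 47.2%, 53.4% and 68.4% with the authors' normalized reactivity, and 68.2% for both with ETC at 50 °C.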

Other observations

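The values below were picked after the data were seen. In the unfiltered pooled profiles, the 16S AUC was 0.644 for G and 0.788 for U at 50 °C, and 0.6 and 0.734 at 55 °C.

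The pooled profiles of the authors hold mutation counts that differ by base from the sums of the replicates. At 50 °C, the unfiltered profile had 3.98 times the summed mutated reads at G with ETC and 0.683 times at U, and the filtered profile 0.557 and 0.602 times. At 16S U1541, next to the anti-Shine-Dalgarno sequence, the rate fell from 4.45% ± 0.232 to 1.59% ± 0.0322 with ETC at 50 °C (limma adjusted p = 1.85e-08), whereas in the unfiltered pooled profile it was higher with ETC, at 4.44% against 0.812%, with an effective depth of 473.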
